A study of Homo sapiens with 16 samples.

How the data were processed

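Gene expression was measured in HK-2 and RPTEC/TERT1 (called RPTEC here), 2 immortalised lines of human proximal tubule epithelium, the nephron segment that takes up filtered glucose and phosphate. Per the labels' protocols, confluent cells were kept for 24 h without serum or supplements and then for 24 h with 500 nM empagliflozin, 500 nM canagliflozin, 10 ng/ml TGF-beta1 (TGFB1 below) or nothing added. Both drugs inhibit the glucose transporter SGLT2, the product of SLC5A2. Each of the 8 groups had 2 arrays, 16 in all. The labels do not say that replicates came from separate cultures, so every p-value measures the spread between these arrays, which may be technical.

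Per the labels, total RNA was labelled with Cy3 and hybridised to 1-colour Agilent 4x44K human expression arrays. The authors deposited scanner output in which each spot has an intensity on a linear scale, and per the file headers it was made with Feature Extraction 9.5.3.1, with spatial and multiplicative detrending. Probe positions are on hg19, per the file headers. The authors also deposited values on a log2 scale, 1 column per array. Its column medians were 6.09, 6.41, 6.08 and 6.09 for replicate 1 and 6.06, 6.06, 6.07 and 6.08 for replicate 2 of HK-2 control, TGFB1, empagliflozin and canagliflozin, and 6.09, 6.08, 6.09 and 6.09 for replicate 1 and 6.07, 6.06, 6.07 and 6.07 for replicate 2 of the same groups of RPTEC. The rank correlation of each column with the scanner signal of its own array was between 0.868 and 0.993, lowest for HK-2 TGFB1 replicate 1, so a higher value means a brighter spot. The log2 scale and the direction were read off these comparisons, genes were not centred, and the normalization between arrays is not given in the sources used here. Every column had a highest value of 16.

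Of 34127 probes, 999 were printed 10 times each and their spots were averaged without outlier spots. Through accessions, 26373 probes matched a RefSeq gene list, and 1973 symbols were updated from it; the others kept the name in the files. Processed signals were divided by the array's 75th percentile, set to a floor of 1 in 64 of it (3.09% of values) and taken to log2. The floor was chosen after the values were seen. Probes well above background on both arrays of at least 1 group were kept (19847 probes), and the probe with the highest mean signal stood for its gene (15763 genes).

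Tests used limma 3.58.1 in R 4.3.3 with data.table (version 1.17.8); figures and tables used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. A model with 1 mean per group was fitted over all 16 arrays (8 residual degrees of freedom), with 2-sided moderated tests and Benjamini-Hochberg adjustment over 15763 genes at a threshold of 0.05. This model, the comparisons, the filter, the alternative analyses, the rule for named genes and 25 gene lists were fixed before the data were examined. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 25 lists of a comparison, and again with an estimated correlation. Among the lists were markers of other nephron segments, podocytes, fibroblasts, endothelial cells and leukocytes.

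The 4 slides each held the 4 arrays of 1 line and 1 replicate number and were each scanned once, so slide, scan and replicate number coincide within a line. Across genes, the differences between replicates of a group correlated with those of the other groups of the line at 0.834 to 0.921 in HK-2 (without the TGFB1 group) and at 0.525 to 0.739 in RPTEC. The slide was therefore also fitted as a block within each line, as batches require. There are only 2 pairs per line. Each treatment, and the control, held 1 place over the slides of a line. Place on the slide and treatment therefore cannot be told apart in any comparison within a line. Likeness of the 2 slides does not separate them. Array quality singled out HK-2 TGFB1 replicate 1, with 5250 of 43118 spots well above background against 19876 to 26319 on the other 15 arrays. The other arrays of its slide were dimmer too, with 19876 to 20897 such spots against 24852 to 26319 on the remaining slides.

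A further fit of the 15 other arrays with slide terms (5 residual degrees of freedom) is given beside most results and called the 15-array fit; it cannot compare the untreated lines. It was adopted after the counts of the 16-array fit, the 15 arrays without slide terms, the 16 arrays with slide terms and the deposited values had been seen, and it gave the most calls of these. The grounds were the shared slides and the low signal of HK-2 TGFB1 replicate 1. For TGFB1, empagliflozin and canagliflozin in HK-2 the counts were 49, 0 and 0 in the 16-array fit, 225, 0 and 0 with slide terms, 291, 0 and 0 for 15 arrays without slide terms, and 1959, 1030 and 1137 in the 15-array fit. In RPTEC they were 2, 0 and 0, then 2, 0 and 0, then 12, 33 and 8, and 197, 694 and 605. In all, 37 fits across genes were run, of which 10 were other analyses fixed in advance, 16 left out 1 array each and 10 were added later. Among the analyses fixed in advance, the replicate block and the slide as block differ only for the untreated lines and are otherwise the same fit. In the 15-array fit the HK-2 TGFB1 group is 1 array, assumed to vary like the other groups, and the spread is shared between lines. The fixed 16-array fit remains the result of each comparison.

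Genes named for a comparison are the 12 largest rises and 12 largest falls in log2 among called genes whose arrays of 1 group all lie on 1 side of the other group's (6 and 6 for the comparison of the lines and for the means of both lines). Arrays in groups of 2 separate so in 33.3% of cases by chance. Where fewer than 5 genes passed, those that passed and the 5 with the smallest p are named. Up to 4 members with the smallest p are named from each list described. SLC5A2, SLC5A1, THBS1, TNC and PDGFB were always named, the last 3 known from a publication on these arrays and so not independent evidence. Transcripts without a current gene symbol are not named, and some genes that the rule selects are not reported here.

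The scripts were tested on simulated data for TGFB1 in RPTEC, among 15763 genes and with no dim array. The 16-array fit recovered 9 of 100 genes changed by 1 log2 unit and 62 of 100 changed by 2, with 0 false calls. The 15-array fit recovered 86 and 99 of 100, with 13 false calls. The simulated values were drawn from that same fit, with 1 spread per gene for both lines. They therefore do not test whether the lines share a spread. Camera gave an unadjusted p under 0.05 for 0 of 100 random lists of 30 genes. The simulated genes varied independently of each other, so this does not test lists of correlated genes. Alternatives were normexp background correction with an offset of 50, quantile normalization, the deposited values, no filter, a filter requiring every array above background (3681 probes), the mean of a gene's probes, each line fitted alone, slide blocks, trended robust variances and leaving out each array. A smaller floor of 1 in 256 was added later. Negative control spots and probes that never passed the filter entered no comparison.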

Results

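TGFB1 raised 19 genes in HK-2 over all 16 arrays, COL1A1, PMEPA1 and IL11 among them, and lowered 30, among them the phosphate transporter gene SLC34A2. In RPTEC, 2 genes rose with TGFB1 over all 16 arrays. Neither inhibitor at 500 nM changed a gene past the threshold over all 16 arrays in either line. That model shares 1 spread over all groups, so the dim array, HK-2 TGFB1 replicate 1, widens the error of every comparison. The median standard error of the inhibitor comparisons was 0.665 with that array and 0.314 without it, both without slide terms. These counts of 0 are therefore weak evidence that the inhibitors changed nothing. In the 15-array fit with slide terms, both inhibitors lowered ACMSD, whose product diverts tryptophan breakdown away from NAD synthesis, in both lines. That fit was adopted after counts had been seen and shares its spread between lines. With HK-2 fitted alone and slide terms, 0 genes passed for either inhibitor. ACMSD also fell with TGFB1 in HK-2 over all 16 arrays. Place on the slide and treatment cannot be told apart in any of these comparisons within a line. The untreated lines differed in 1691 genes.

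Signal was lower on the slide of HK-2 replicate 1 than on the other slides, and lowest on 1 array. The HK-2 control, empagliflozin and canagliflozin arrays of replicate 1 had 47.1%, 48.5% and 46.1% of spots well above background. Arrays of the other slides had 57.6% to 61.0%. Their 75th percentiles of intensity were 473 to 633, against 152, 175 and 136 on those HK-2 arrays. HK-2 TGFB1 replicate 1 had 12.2% of spots well above background, a 75th percentile of intensity of 7.43 against 136 to 633 on the other 15 arrays, and a spike-in slope of 0 against 1.01 to 1.12. Replicates of a group correlated at 0.941 to 0.989 on the log2 scale except in that group (0.522). Of the genes named in advance, SLC5A1 was well above background on 0 of 16 arrays, SLC5A2 and PDGFB on 15, and THBS1 and TNC on 16. A gene not well above background on any array of 1 group has its fold given as a lower bound, "at least", against the lowest signal that passed. For rises with TGFB1 in HK-2 the bound is not strict, as described there. All values are log2 differences with standard errors unless stated otherwise.

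**Figure D1:**
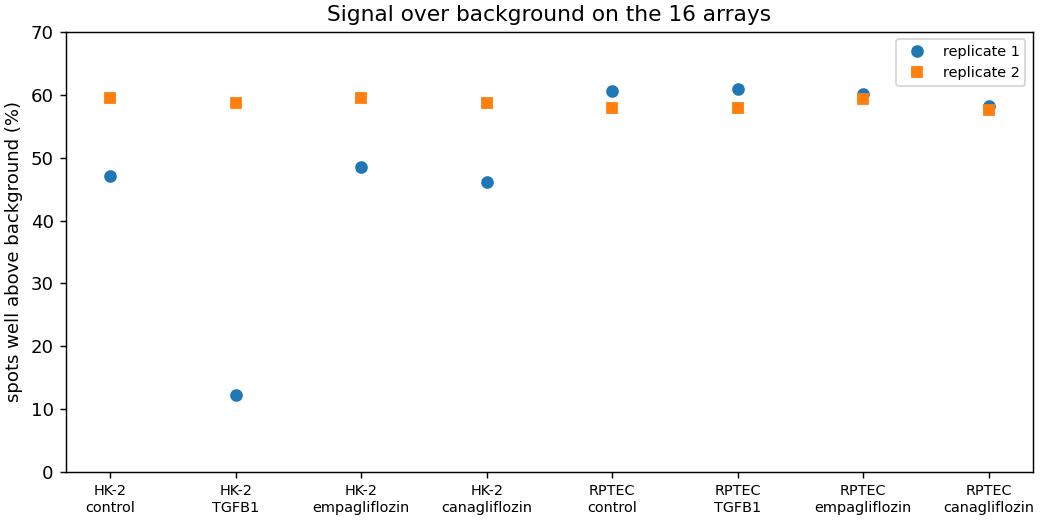
Percent of spots well above background on each of the 16 arrays. HK-2 TGFB1 replicate 1 stood at 12.2%.

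Between the untreated lines, CDH1, which encodes E-cadherin, was higher in RPTEC by 9.32 (SE 0.68, adjusted p = 6.39e-06), the tight junction gene OCLN at least 31.5-fold (adjusted p = 1.65e-06) and the kidney transcription factor PAX2 at least 96.1-fold. CDH2, which encodes N-cadherin, was at least 166-fold lower in RPTEC. In all, 995 genes were higher and 696 lower in RPTEC. The lines never shared a slide. Each had 2, between which the control arrays differed with an SD of 0.95 in HK-2 and 0.51 in RPTEC, and anything common to both slides of 1 line remains part of the difference. SPON1 was at least 788-fold, SLPI at least 377-fold, AGR2 at least 502-fold and FGFBP1 at least 318-fold higher, and ALDH1A1 differed by 9.86 (SE 0.29, adjusted p = 5.57e-08). DHRS3 was at least 800-fold, IRX4 at least 548-fold, G0S2 at least 444-fold, PLBD1 at least 278-fold and TCAM1P at least 249-fold lower, and CLDN11 differed by -8.65 (SE 1.17). THBS1 was higher in RPTEC by 3.33 (SE 0.66, adjusted p = 0.00734), while SLC5A2 did not pass (-0.22, SE 0.81, adjusted p = 0.944), nor did TNC (-0.38) or PDGFB (-0.38).

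Of 27 epithelial genes measured, 15 were higher in RPTEC, 0 lower and 12 did not pass (median 3.06, adjusted p = 4.08e-15 for the list and adjusted p = 0.00188 with an estimated correlation). This was the 1 list that passed with both forms of the test between the lines. The plan fixed in advance set no list test between the untreated lines. Of 39 interferon genes, 10 were higher (IFITM3 by 5.22, SE 0.31), 1 lower and 28 did not pass (adjusted p = 3.31e-04, but adjusted p = 0.490 with an estimated correlation). Of 33 genes of cholesterol and lipid synthesis, 8 were higher, such as MVK by 2.57 (SE 0.36), and 25 did not pass (adjusted p = 4.55e-06, but adjusted p = 0.518 with an estimated correlation). Of 32 genes of the unfolded protein and ATF4 response, 9 were lower, such as ASNS, the asparagine synthetase gene (-3.73, SE 0.45), and 23 did not pass (adjusted p = 5.43e-04, but adjusted p = 0.490 with an estimated correlation). Of 39 proliferation genes, 4 were lower, such as MCM2 (-2.54, SE 0.47), and 35 did not pass (adjusted p = 1.51e-06, but adjusted p = 0.581 with an estimated correlation). Markers of other nephron segments were higher in 3 of 4 genes (median 2.71, adjusted p = 9.998e-04, but adjusted p = 0.0725 with an estimated correlation) and podocyte markers in 2 of 5 (median 1.58, adjusted p = 0.00508, but adjusted p = 0.0970 with an estimated correlation). Leukocyte markers were lower in 3 of 8 (median -1.03, adjusted p = 0.0487, but adjusted p = 0.518 with an estimated correlation). Respiratory chain genes passed narrowly with 1 of 45 members higher (median 0.51, adjusted p = 0.0499, but adjusted p = 0.640 with an estimated correlation). Fibroblast markers (2 of 8 higher, 3 lower, adjusted p = 0.296) and endothelial markers (1 of 4 higher, adjusted p = 0.209) did not pass.

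TGFB1 in HK-2 raised the collagen gene COL1A1 by 3.56 (SE 0.36, adjusted p = 0.00503). PMEPA1, an inhibitor of SMAD signalling, rose by 6.71 (SE 0.88), the cytokine gene IL11 by 5.02 (SE 0.77, adjusted p = 0.0255), the Notch ligand gene JAG1 by 3.72 (SE 0.53) and ANKRD1 by 3.64 (SE 0.39). In all, 19 genes rose and 30 fell over all 16 arrays, and the median of all genes lay at -0.39. Other large rises were ODAPH (at least 60.1-fold, adjusted p = 7.99e-04), CGB3 (at least 26.3-fold), ANXA8L1 (at least 9.77-fold), SIGLEC11 (at least 7.99-fold) and EPPK1 (4.41, SE 0.75). These bounds are not strict, because their means include the dim array, whose values were divided by a 75th percentile of only 7.43. SLC5A1, not well above background on any array, had -1.34 on the dim array against -6 on both HK-2 control arrays. Among the falls listed here with a log2 difference, that of the transcription factor gene HLF was largest (-5.78, SE 0.80, adjusted p = 0.0130). The sodium channel gene SCNN1A fell (-3.45, SE 0.46), as did the basement membrane gene NID2 (-4.03, SE 0.68), WDR86 (-4.77), DSCAML1 (-4.11) and SPTLC3 (-3.49). Against detection, ABCA12 was at least 2.73-fold, CNR1 at least 2.10-fold, ACMSD at least 1.91-fold, SLC34A2 at least 1.26-fold, ARHGAP6 at least 1.07-fold and KLHL14 at least 1.03-fold lower. SLC5A2 (1.06, SE 0.81, adjusted p = 0.372), THBS1 (2.11, SE 0.66, adjusted p = 0.248), TNC (2.64, SE 0.61, adjusted p = 0.123) and PDGFB (1.71, SE 0.44, adjusted p = 0.177) did not pass. The 15-array fit had 908 rises and 1051 falls, including all 49 above, and the median of all genes lay at -0.03. There THBS1 rose by 1.54 (SE 0.21, adjusted p = 0.00288), TNC by 2.61 (SE 0.36) and PDGFB by 1.90 (SE 0.24), and SLC5A2 did not pass (0.08, SE 0.14, adjusted p = 0.778).

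Among 34 TGFB/SMAD targets measured in HK-2 with TGFB1, 3 rose (PMEPA1 and IL11 among them), 0 fell and 31 did not pass; 14 rose adjusted over the list alone. The list had a median of 1.49 (adjusted p = 3.04e-12, but adjusted p = 0.112 with an estimated correlation), and 0.89 and 1.76 on the separate slides. The 0.89 is from the slide of the dim array. Across all genes the changes on the separate slides correlated at 0.0488. Of 40 extracellular matrix genes, 2 rose (COL1A1 and MMP9), 0 fell and 38 did not pass, with 9 higher and 2 lower adjusted over the list alone (median 0.93, adjusted p = 5.86e-06, but adjusted p = 0.0996 with an estimated correlation). Of 20 mesenchymal and contractile genes 0 passed over all genes, and 5 rose and 1 fell adjusted over the list alone (median 1.11, adjusted p = 3.45e-04, but adjusted p = 0.0519 with an estimated correlation). With slide terms, 23 TGFB/SMAD targets rose in the 15-array fit and 0 fell, among them GADD45B by 2.46 (SE 0.14), BMF by 2.67 (SE 0.15) and LTBP2 by 2.96 (SE 0.32). There 21 matrix genes rose and 3 fell (LOX by 2.93, SE 0.17; COL4A1 by 2.47, SE 0.16), and 12 mesenchymal and contractile genes rose and 1 fell (TAGLN by 2.68, SE 0.25; SNAI1 by 2.10, SE 0.20). The mesenchymal list was the 1 that passed there with an estimated correlation (adjusted p = 0.0403).

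Of 32 proximal tubule transport genes measured in HK-2 with TGFB1, 1 fell (SLC34A2) and 31 did not pass; adjusted over the list alone, 1 rose and 8 fell. The median was -0.00, the mean -0.44 and the list did not pass (adjusted p = 0.658); the slides differed, with medians of 0.02 on that of the dim array and -0.66 on the other. In the 15-array fit 10 fell and 1 rose (adjusted p = 6.70e-05, but adjusted p = 0.0653 with an estimated correlation). The glucose transporter gene SLC2A2 was at least 13.5-fold lower there, the urate transporter gene SLC17A3 at least 21-fold and SLC34A2 at least 9.22-fold, and the endocytic receptor gene LRP2 fell by 2.28 (SE 0.20). These fold bounds set both HK-2 control arrays against TGFB1 replicate 2 without slide terms. The difference between slides therefore enters the bounds, unlike the value of LRP2 in the 15-array fit. Interferon genes fell in 12 of 39 cases and rose in 2 in that fit, such as IFITM1 (-2.08, SE 0.17) and IFIT2 (-1.96, SE 0.23), with adjusted p = 0.0308 for the list but adjusted p = 0.439 with an estimated correlation.

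**Figure D2:**
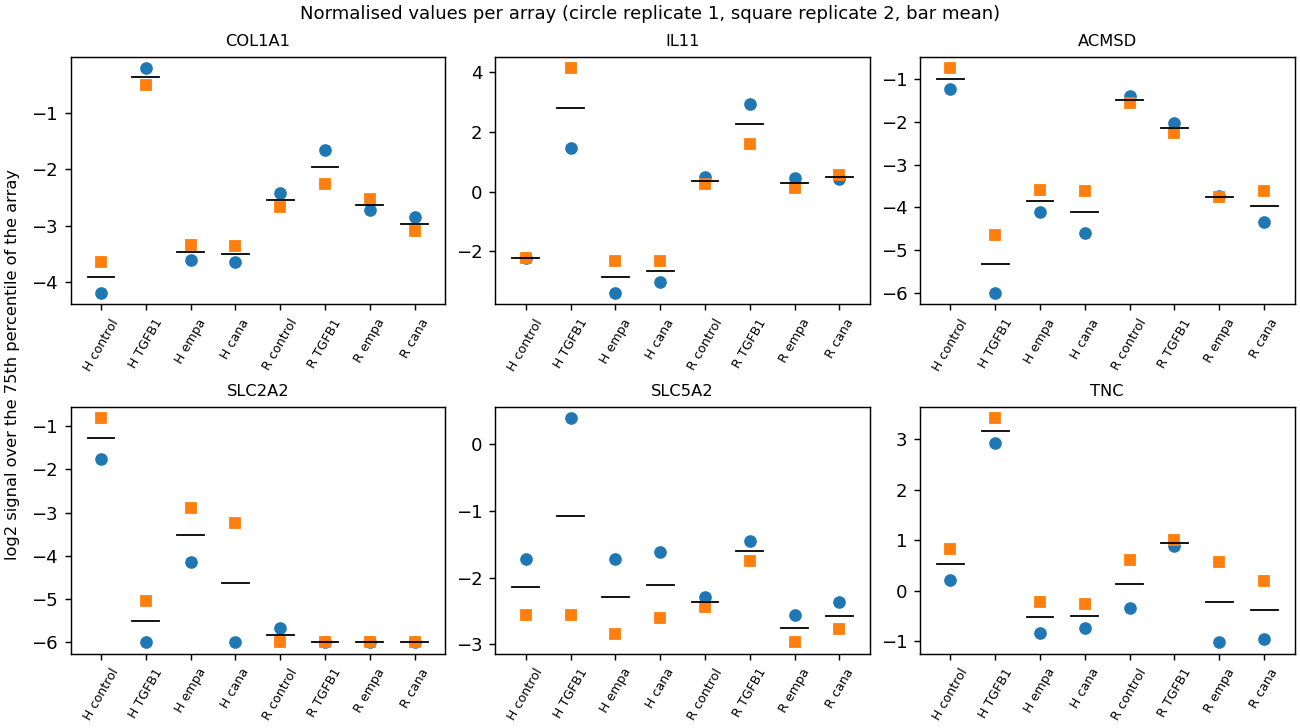
Log2 signal relative to the 75th percentile of the array for COL1A1, IL11, ACMSD, SLC2A2, SLC5A2 and TNC on each array, chosen after their values were seen. H marks HK-2 and R marks RPTEC.

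In RPTEC, TGFB1 raised IGFBP5, which encodes a binding protein of insulin-like growth factors, at least 6.08-fold (adjusted p = 0.00610), and the surface antigen gene GPA33 at least 4.55-fold (adjusted p = 0.0133). No gene fell over all 16 arrays. The next smallest p belonged to ANXA8L1 (4.37, SE 0.62), FZD10 (3.33), HS3ST2 (at least 3.92-fold) and RASSF4 (at least 7.77-fold), each at adjusted p = 0.122, and MMP9 (2.48, SE 0.40, adjusted p = 0.178). SLC5A2 (0.76), THBS1 (0.32), TNC (0.81) and PDGFB (1.19) had adjusted p = 1. With RPTEC fitted alone and slide terms 2 genes passed, or 62 without genes at 1 value on every array of the line. With slide terms on 15 arrays, where the spread is shared between lines, 161 genes rose and 36 fell. The activin gene INHBA rose by 3.44 (SE 0.34), the fibronectin gene FN1 at least 4.74-fold (adjusted p = 0.00178), SPOCD1 at least 5.62-fold, PDGFB by 1.19 (SE 0.18, adjusted p = 0.0286) and SLC5A2 by 0.76 (SE 0.11, adjusted p = 0.0235). Falls included LRP2 (-1.15, SE 0.15, adjusted p = 0.0167), the activin antagonist gene FST (at least 2.93-fold) and DACH2 (at least 5.18-fold, adjusted p = 0.0384).

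As lists, 4 sets of genes passed with TGFB1 in RPTEC with both forms of the test. TGFB/SMAD targets had a median of 0.64 (adjusted p = 9.23e-39, and adjusted p = 0.00592 with an estimated correlation), and 1 rose adjusted over the list alone. Matrix genes had a median of 0.38 (adjusted p = 7.95e-30, and adjusted p = 0.00103 with an estimated correlation), and 4 rose adjusted over the list alone. NF-kB cytokine genes had a median of 0.74 (adjusted p = 4.45e-19, and adjusted p = 0.0114 with an estimated correlation), and mesenchymal and contractile genes 0.14 (adjusted p = 3.21e-04, and adjusted p = 0.0140 with an estimated correlation). None of their members passed over all genes. On the separate slides the medians were 1.02 and 0.44, 0.59 and 0.39, and 0.97 and 0.43 for the TGFB/SMAD, matrix and NF-kB lists. None of these 4 passed in the 15-array fit with an estimated correlation, and 11 TGFB/SMAD targets (such as BMF by 1.77, SE 0.12), 11 matrix genes (COL7A1 by 1.72, SE 0.19), 6 NF-kB genes (ICAM1 by 1.18, SE 0.15; IL6 by 0.85, SE 0.12; IL32 by 0.99, SE 0.15) and 2 mesenchymal genes rose. Hypoxia genes (median 0.13, adjusted p = 0.00208, but adjusted p = 0.497 with an estimated correlation), p53 and senescence genes (0.19, adjusted p = 0.0170, but adjusted p = 0.295 with an estimated correlation) and endothelial markers (-0.12, adjusted p = 0.0282, but adjusted p = 0.155 with an estimated correlation) passed with the preset correlation.

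Empagliflozin in HK-2 changed 0 genes over all 16 arrays by limma, with 117 genes at an unadjusted p under 0.05. From here on, such counts over all 16 arrays were 0.121% to 3.25% of genes. By chance alone a share of 0.05 would lie there, so these counts are not evidence of change. For empagliflozin in HK-2 the share was 0.742%. Among genes with a current symbol, ACMSD had the smallest p (-2.86, SE 0.51, adjusted p = 1), followed by DHRS2 (2.63, SE 0.60), EFR3B (at least 3.54-fold higher), ZFHX4-AS1 (at least 1.55-fold lower) and MMP20, not well above background in either group. The 15-array fit had 509 rises and 521 falls: ACMSD fell (-2.86, SE 0.23, adjusted p = 0.00254), as did SLC2A2 (-2.24, SE 0.36, adjusted p = 0.0174) and SLC17A3 (-2.51, SE 0.44, adjusted p = 0.0215), and DHRS2 rose by 2.63 (SE 0.37). SLC5A2 differed by -0.14, THBS1 by -0.48, TNC by -1.05 and PDGFB by -0.66, with adjusted p = 1 over 16 arrays; TNC (SE 0.28, adjusted p = 0.0617) did not pass in the 15-array fit either. The 15-array fit shares its spread between lines, and with HK-2 fitted alone 0 genes passed for either inhibitor.

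Proximal tubule transport genes lay lower with empagliflozin in HK-2 (median -0.18, mean -0.55, adjusted p = 1.70e-06, and adjusted p = 0.00664 with an estimated correlation), the 1 list that passed with both forms of the test. None of its 32 members passed over 16 arrays; 5 fell in the 15-array fit, among them SLC2A2, SLC17A3, SLC34A2 (-1.24, SE 0.20) and the cystine transporter gene SLC3A1 (-1.38, SE 0.16), where the list had adjusted p = 0.241 with an estimated correlation. Matrix genes (median -0.24, adjusted p = 2.87e-04, but adjusted p = 0.137 with an estimated correlation), NF-kB cytokine genes (-0.26, adjusted p = 0.00339, but adjusted p = 0.382 with an estimated correlation), genes of the unfolded protein response (-0.16, adjusted p = 0.00339, but adjusted p = 0.434 with an estimated correlation) and immediate early genes (-0.28, adjusted p = 3.67e-05, but adjusted p = 0.143 with an estimated correlation) lay lower. In the 15-array fit 4, 3, 5 and 4 members of these lists fell, such as THBS2 (-0.94, SE 0.08), IL6 (-1.12, SE 0.12), XBP1 (-0.61, SE 0.10) and MYC (-0.86, SE 0.13), and 1 matrix gene rose. Proliferation genes lay higher (median 0.63, adjusted p = 1.77e-05, but adjusted p = 0.619 with an estimated correlation), with FOXM1 (1.11, SE 0.25) and AURKA (0.91, SE 0.22) the 2 of 39 that rose in the 15-array fit. Heat shock and metallothionein genes lay higher as well (0.18, adjusted p = 0.00739, but adjusted p = 0.0940 with an estimated correlation), and 4 rose in that fit, such as HSPA1B by 1.05 (SE 0.11) and DNAJB1 by 0.70 (SE 0.10). Podocyte markers lay higher beside them (0.30, adjusted p = 0.00339, but adjusted p = 0.0940 with an estimated correlation). Epithelial genes (-0.04, adjusted p = 0.0131, but adjusted p = 0.145 with an estimated correlation) and tubular injury genes (-0.11, adjusted p = 0.0275, but adjusted p = 0.281 with an estimated correlation) lay slightly lower.

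With canagliflozin in HK-2, ACMSD (-3.13, SE 0.51, adjusted p = 0.765), ZFHX4-AS1 (at least 1.73-fold lower), DHRS2 (2.75), SLC2A2 (-3.33, SE 0.78) and LIMCH1 (1.43) had the smallest p among genes with a current symbol; the smallest adjusted p overall was 0.707. By limma 0 genes passed over all 16 arrays, with 112 at an unadjusted p under 0.05. The 15-array fit had 520 rises and 617 falls, with SLC2A2 at -3.33 (SE 0.36, adjusted p = 0.00574), ACMSD at -3.13 (SE 0.23, adjusted p = 0.00175) and LIMCH1 at 1.43 (SE 0.09, adjusted p = 0.00109). SLC5A2 (0.04), THBS1 (-0.44), TNC (-1.02) and PDGFB (-0.48) did not pass in either fit. Proximal tubule transport genes again passed as a list with both forms of the test (median -0.27, adjusted p = 1.13e-04, and adjusted p = 0.0238 with an estimated correlation), with 1 member lower adjusted over the list alone. The median was 0.051 under the strict filter (adjusted p = 0.852) and ranged from -0.65 to -0.077 when 1 array was left out. In the 15-array fit 5 fell (SLC3A1 at -1.34, SE 0.16; SLC34A2 at -1.30, SE 0.20), but the list had adjusted p = 0.305 with an estimated correlation.

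Further lists of canagliflozin in HK-2 moved as with empagliflozin and passed with the preset correlation alone. Matrix genes had a median of -0.20 (adjusted p = 0.00744, but adjusted p = 0.241 with an estimated correlation), NF-kB genes -0.24 (adjusted p = 0.0165, but adjusted p = 0.563 with an estimated correlation), unfolded protein response genes -0.06 (adjusted p = 0.0118, but adjusted p = 0.563 with an estimated correlation) and immediate early genes -0.22 (adjusted p = 1.10e-04, but adjusted p = 0.178 with an estimated correlation). Proliferation genes had a median of 0.55 (adjusted p = 3.55e-04, but adjusted p = 0.775 with an estimated correlation), heat shock and metallothionein genes 0.23 (adjusted p = 0.00901, but adjusted p = 0.0900 with an estimated correlation) and podocyte markers 0.43 (adjusted p = 0.00367, but adjusted p = 0.0900 with an estimated correlation). Epithelial genes had a median of 0.00 and a mean of -0.14 (adjusted p = 0.0330 downward, but adjusted p = 0.241 with an estimated correlation). In the 15-array fit 4 matrix, 3 NF-kB, 5 unfolded protein response and 5 immediate early genes fell, among them IL6 (-1.15, SE 0.12) and VCAM1 (-1.46), 3 proliferation and 3 heat shock genes rose, and 2 matrix genes rose.

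Empagliflozin in RPTEC changed 0 genes over all 16 arrays by limma, with 163 at an unadjusted p under 0.05 and a smallest adjusted p of 0.753, for TRIM29 (-2.18, SE 0.33). The next were ADH6 (at least 2.69-fold lower), PRRX2 (at least 6.06-fold lower), DACH2 (at least 4.42-fold lower) and the membrane protein gene TM4SF4 (-3.44, SE 0.65). Rises numbered 308 and falls 386 in the 15-array fit. TM4SF4 fell (-3.44, SE 0.27, adjusted p = 0.00202), SMOC2, which encodes a matrix-associated calcium-binding protein, was at least 9.84-fold lower, and ACMSD fell (-2.26, SE 0.23, adjusted p = 0.00283). SLC5A2 (-0.40), THBS1 (-0.41), TNC (-0.36) and PDGFB (-0.27) did not pass in either fit. Matrix genes lay lower (median -0.15, adjusted p = 3.40e-04, but adjusted p = 0.240 with an estimated correlation), and 6 of 40 fell and 0 rose in the 15-array fit, including the collagen cross-linking gene LOX (at least 2.29-fold), MFAP5 (-1.52, SE 0.18) and ADAMTS1 (-1.28, SE 0.14). NF-kB genes (-0.23, adjusted p = 0.0254, but adjusted p = 0.695 with an estimated correlation) had 2 falls in that fit, CXCL5 (-1.17, SE 0.24) and ICAM1 (-0.69, SE 0.15). Proliferation genes lay lower (-0.40, adjusted p = 6.37e-05, but adjusted p = 0.856 with an estimated correlation) with 0 of 39 members passing in either fit. In fits without slide terms the list turned and passed upward when empagliflozin replicate 1 was left out (median 0.35, adjusted p = 0.00971); within slides it was negative on both. Epithelial genes (-0.10, adjusted p = 0.0240, but adjusted p = 0.265 with an estimated correlation) and markers of other nephron segments (-0.42, adjusted p = 0.0141, but adjusted p = 0.240 with an estimated correlation) lay lower. Of the immediate early genes 3 of 22 rose in the 15-array fit, among them FOS by 1.49 (SE 0.14) and EGR1 by 1.63 (SE 0.25).

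Canagliflozin in RPTEC changed 0 genes over all 16 arrays by limma, with 139 at an unadjusted p under 0.05. TRIM29 (-2.05, SE 0.33), CAPN12 (at least 1.86-fold lower) and ADH6 (at least 2.82-fold lower) had adjusted p = 0.894, and DACH2 (at least 4.64-fold lower) and TM4SF4 (-3.39, SE 0.65) followed. Rises numbered 235 and falls 370 in the 15-array fit, among them SMOC2 (at least 12.2-fold lower), TM4SF4 (-3.39, SE 0.27, adjusted p = 0.00341), ACMSD (-2.49, SE 0.23, adjusted p = 0.00341) and EGR1, which rose by 1.67 (SE 0.25, adjusted p = 0.0148). SLC5A2 (-0.21), THBS1 (-0.33), TNC (-0.52) and PDGFB (-0.51) did not pass in either fit. Matrix genes lay lower (median -0.27, adjusted p = 6.02e-05, but adjusted p = 0.161 with an estimated correlation), and 6 fell in the 15-array fit, as did 2 NF-kB genes (list median -0.25, adjusted p = 0.00206, but adjusted p = 0.326 with an estimated correlation). Proliferation genes (-0.50, adjusted p = 4.37e-06, but adjusted p = 0.654 with an estimated correlation) and markers of other nephron segments (-0.61, adjusted p = 3.42e-04, but adjusted p = 0.0787 with an estimated correlation) lay lower. Without slide terms and without canagliflozin replicate 1 the proliferation list passed upward (median 0.41, adjusted p = 6.78e-04), and within slides it was negative on both. Epithelial genes had a median of -0.00 and a mean of -0.20 (adjusted p = 0.0121, but adjusted p = 0.217 with an estimated correlation).

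**Figure D3:**
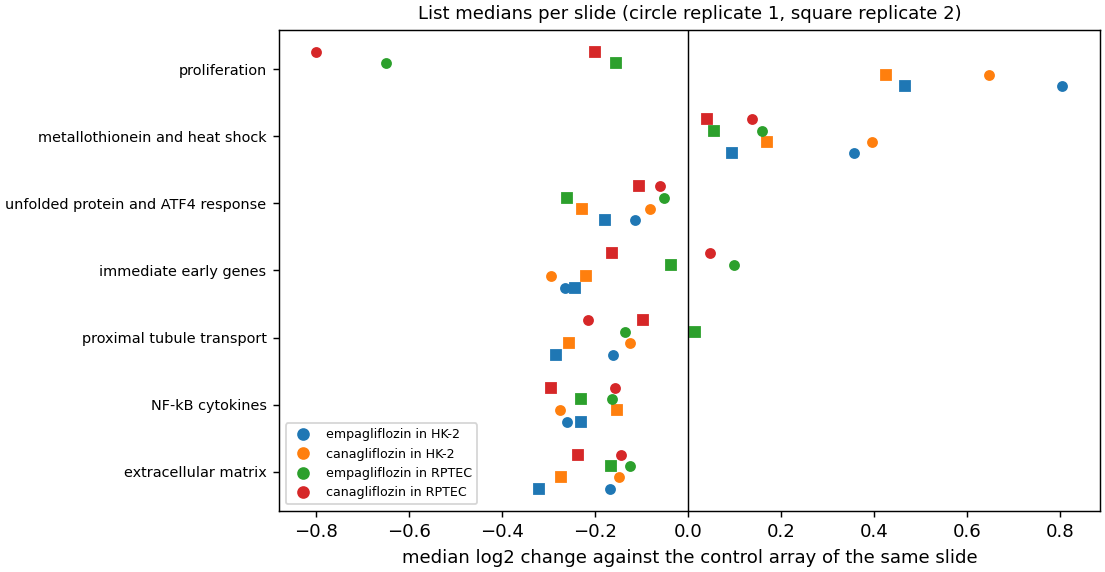
Median log2 difference from the control array of the same slide for 7 gene lists under each inhibitor in each line, chosen after their values were seen. The points are the slides of replicates 1 and 2.

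Per slide, the median of the proliferation list was 0.81 and 0.47 with empagliflozin and 0.65 and 0.43 with canagliflozin in HK-2, and -0.65 and -0.15 and then -0.80 and -0.20 in RPTEC. With TGFB1 in RPTEC the same list lay at 0.25 (33 of 39 genes positive) and -0.39 (0 of 39). The list can thus shift as a whole between arrays, so like signs on 2 slides are weak evidence of an effect on it. Proximal tubule transport genes lay at -0.16 and -0.28 with empagliflozin and at -0.12 and -0.26 with canagliflozin in HK-2. In RPTEC these genes lay at -0.14 and 0.02 with empagliflozin and at -0.22 and -0.10 with canagliflozin. Matrix genes lay at -0.17 and -0.32 and at -0.15 and -0.27 in HK-2, and at -0.13 and -0.17 and at -0.14 and -0.24 in RPTEC.

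Empagliflozin and canagliflozin are C-aryl glucosides, and both were given at 500 nM. The differences between these compounds include the outer ring, a tetrahydrofuranyloxy benzyl group against a fluorophenyl thiophene. Their direct comparison gave 0 genes by limma over all 16 arrays in HK-2 (19 at an unadjusted p under 0.05) and in RPTEC (30). Among genes with a current symbol, the smallest p in HK-2 belonged to CACNA2D3 (at least 1.33-fold), CSGALNACT1, not well above background with either inhibitor, and BTG4 (at least 2.30-fold), and in RPTEC to MYL9 (at least 2.19-fold) and MXRA8 (at least 3.35-fold), each at adjusted p = 1; the smallest adjusted p overall in HK-2 was 0.707. No list differed (smallest adjusted p = 0.664 in HK-2 and 0.368 in RPTEC). The 95% interval of the difference had a median half-width of 1.47 over 16 arrays and lay within 2-fold for 13.7% of genes in HK-2 and 13.6% in RPTEC. With 15 arrays and slide terms the half-width was 0.32, with 94.2% and 93.6% of genes within 2-fold; 0 genes differed in HK-2 (475 at an unadjusted p under 0.05) and 16 in RPTEC, 15 higher and 1 lower with empagliflozin. Among these were TULP1 (at least 3.51-fold, adjusted p = 0.00130), OR2G2 (at least 2.96-fold, adjusted p = 0.00395) and ALX1 (at least 4.04-fold, adjusted p = 0.0218). The 16 became 0 with the deposited values, with normexp and with probes above background on all 15 arrays, and 1 with the smaller floor. Olfactory receptor probes, of which OR2G2 is 1, were brighter as a group on the RPTEC empagliflozin arrays (median net intensity 4.00 and 5.91) than on the RPTEC canagliflozin arrays (1.35 and 2.50), but not in HK-2 (-0.15 and 0.639 against 1.14 and 0.688).

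Fold changes of the inhibitors in the 15-array fit, without the dim array, correlated across genes at 0.86 in HK-2 and 0.767 in RPTEC. Shared control arrays alone gave 0.502 in simulations; the covariances were 0.128 and 0.104 against 0.0237 simulated. With both inhibitors, 351 genes rose and 412 fell in HK-2 in the 15-array fit (16.8 and 20.4 for independent lists), and 144 and 292 in RPTEC (4.59 and 9.06). The controls could not be split, with 1 array per part, so part of this excess may come from them. Between lines, which share no arrays, the correlation was 0.206 for empagliflozin, 0.214 for canagliflozin and 0.372 for TGFB1 (0.123 over all 16 arrays). Within HK-2 the TGFB1 fold changes correlated with those of empagliflozin at 0.268 and of canagliflozin at 0.284 (simulated 0.387 and 0.386; 0.0386 and 0.122 over all 16 arrays), with covariances of 0.0618 and 0.0668 against 0.0236 and 0.0235 simulated. Within RPTEC the correlations were 0.162 and 0.118 (simulated 0.502 and 0.501), with covariances of 0.0195 and 0.0131 against 0.0237 and 0.0236 simulated.

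The response to TGFB1 was tested for a difference between lines. Over all 16 arrays 0 genes passed by limma, with 513 at an unadjusted p under 0.05; ABCA12 and IGFBP5 came closest (adjusted p = 0.0800), before CNR1 and GPA33 at adjusted p = 0.138. Of these, ABCA12 and CNR1 were not well above background on any HK-2 TGFB1 array and IGFBP5 and GPA33 on any HK-2 array, so no size of the difference is given. The 15-array fit gave 705 genes, 423 higher and 282 lower in RPTEC, including SLC17A3 and the bile acid receptor gene NR1H4, both not well above background on any HK-2 TGFB1 array. On the slides of replicate 1, 1 of which holds the dim array, TGFB/SMAD targets had medians of 0.89 in HK-2 and 1.02 in RPTEC. On those of replicate 2 they had 1.76 and 0.44. Over all 16 arrays TGFB/SMAD targets responded less in RPTEC (median difference -0.41, adjusted p = 4.46e-04, but adjusted p = 0.562 with an estimated correlation), as did mesenchymal genes (-0.65, adjusted p = 0.0205, but adjusted p = 0.222 with an estimated correlation). With 15 arrays the medians were -1.04 and -0.52, with adjusted p = 0.214 and adjusted p = 0.0745 with an estimated correlation.

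For the inhibitors, 0 genes differed between lines over all 16 arrays by limma, with 77 at an unadjusted p under 0.05 for empagliflozin and 61 for canagliflozin. TRIM29 had the smallest p for both and was not well above background on any HK-2 array, so this restates its values in RPTEC. The 15-array fit gave 188 genes for empagliflozin (96 higher and 92 lower in RPTEC), such as TM4SF4 (adjusted p = 0.0229), and 120 for canagliflozin (56 and 64), such as SLC2A2 (adjusted p = 0.0425). TM4SF4 was not well above background on any HK-2 array and SLC2A2 on any RPTEC array, so each restates the other line. The proliferation list moved apart between the lines, by -1.02 for empagliflozin (adjusted p = 1.12e-13, but adjusted p = 0.524 with an estimated correlation) and -0.91 for canagliflozin (adjusted p = 9.06e-12, but adjusted p = 0.546 with an estimated correlation).

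As a mean of both lines, TGFB1 raised 16 genes and lowered 14 over all 16 arrays. PMEPA1 rose by 4.42 (SE 0.62) and IL11 by 3.46, and SCNN1A fell (-2.19). ODAPH (adjusted p = 0.00153), CGB3 and ANXA8L1 rose as well, and ACMSD (adjusted p = 0.0331), ARHGAP6 and NFE2 fell. No size is given for these 6: ODAPH and CGB3 were not well above background on the control arrays of either line, ANXA8L1 on those of HK-2, and the others on the HK-2 TGFB1 arrays. The mean of both lines gave 0 genes for empagliflozin (207 at an unadjusted p under 0.05) and 0 for canagliflozin (177) by limma. ACMSD had the smallest p for each (-2.56, SE 0.36, adjusted p = 0.435, and -2.81, SE 0.36, adjusted p = 0.191) and lay below control on all arrays of both lines. The 15-array fit gave 1794 and 1754 genes, and 1933 for TGFB1.

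Genes that moved with TGFB1 in 1 line were followed in the other. The 19 genes that rose in HK-2 had a median of 1.11 with TGFB1 in RPTEC (p = 1.62e-06 with an estimated correlation), and the 30 that fell had -0.39 (p = 0.00661 with an estimated correlation). With empagliflozin in RPTEC the 30 lay lower (median -0.22, adjusted p = 2.82e-04, but adjusted p = 0.816 with an estimated correlation) in the direction of TGFB1. The other 3 tests in RPTEC did not pass (smallest adjusted p = 0.1998). The 2 genes that rose with TGFB1 in RPTEC were not well above background on any HK-2 array and could not be followed there. From the 15-array fit up to 100 genes per direction were followed. Genes raised by TGFB1 in HK-2 lay lower in RPTEC, against TGFB1, with empagliflozin (median -0.06) and canagliflozin (-0.07, each adjusted p = 0.0163, but adjusted p = 0.592 with an estimated correlation). Genes raised by TGFB1 in RPTEC lay higher with TGFB1 in HK-2 (mean 1.34, p = 0.0521 with an estimated correlation) and lower there with empagliflozin (median -0.15, adjusted p = 0.00238, but adjusted p = 0.592 with an estimated correlation) and canagliflozin (median -0.07, adjusted p = 0.0119, but adjusted p = 0.592 with an estimated correlation). Genes lowered by TGFB1 in HK-2 lay lower too, along with TGFB1, with empagliflozin (median -0.20, adjusted p = 1.93e-06, but adjusted p = 0.592 with an estimated correlation) and canagliflozin in RPTEC (median -0.07, adjusted p = 0.00271, but adjusted p = 0.592 with an estimated correlation), so the lists gave no single direction against or along with TGFB1.

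For 9 of the 25 lists no treatment in either line gave a list past the threshold over all 16 arrays. These were interferon genes (smallest adjusted p = 0.242), glycolysis (0.262), gluconeogenesis and ketone metabolism (0.715), fatty acid oxidation (0.189), cholesterol and lipid synthesis (0.166), respiratory chain (0.0862), NRF2 and oxidative stress genes (0.129), fibroblast markers (0.113) and leukocyte markers (0.155). One member of the NRF2 list, AKR1C1, fell with TGFB1 in HK-2 (adjusted p = 0.00822) and was not well above background on either TGFB1 array.

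Named probes lie, on hg19, at 48261509 to 48261568 of chromosome 17 (COL1A1), 135630187 to 135655945 of chromosome 2 (ACMSD), 25679941 to 25680000 of chromosome 4 (SLC34A2), 31502023 to 31502082 of chromosome 16 (SLC5A2) and 149216588 to 149216647 of chromosome 3 (TM4SF4). Their place in exons or untranslated regions is not given in the sources used here.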

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

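The tests on the dim array, on shared control arrays and on the place of an array on its slide were chosen after the result was seen, and the 15-array fit was chosen after the counts were seen.

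Responses that differed between the lines were found by tests of the difference itself. The response to TGFB1 in the 15-array fit differed between RPTEC and HK-2 in 705 genes, to empagliflozin in 188 and to canagliflozin in 120; over all 16 arrays limma gave 0 genes for each, with 513, 77 and 61 at an unadjusted p under 0.05. As lists, with the preset correlation and over 16 arrays, the response to TGFB1 in RPTEC lay below that in HK-2 by medians of -0.41 for TGFB/SMAD targets and -0.65 for mesenchymal and contractile genes. The slides of replicate 1 did not show this for TGFB/SMAD targets, with medians of 0.89 in HK-2 (with the dim array) and 1.02 in RPTEC. For empagliflozin the medians of the difference were 0.16 for proximal tubule transport, -1.02 for proliferation, 0.35 for immediate early genes, -0.63 for markers of other nephron segments and -0.43 for podocyte markers. For canagliflozin they were -0.91 for proliferation, 0.47 for immediate early genes, -0.55 for markers of other nephron segments and -0.44 for podocyte markers. None of these lists passed with an estimated correlation (adjusted p between 0.0615 and 0.562).

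Olfactory receptor probes, which entered no comparison as a group, had 98 spots well above background on the RPTEC empagliflozin arrays (49 on each) against 47 and 34 on the RPTEC control arrays, of 419 such spots per array. The TGFB1 arrays had 51 and 32 and the canagliflozin arrays 43 and 34, so on the slide of replicate 1 the count did not set empagliflozin apart. Additive background was tested on signals with the local background already subtracted, so the test covers only what was left after that. Such a remainder was argued against: negative control spots rose by 0.1676 intensity units against 2.21 for olfactory receptor spots on the slide of replicate 1. The ratios of these rises were 0.0758 and 0.0929 on the 2 slides. Before subtraction, negative control spots rose by 0.0441 and 0.0463 log2 units and olfactory receptor spots by 0.1115 and 0.2118. Signal from sequence other than the named transcript may contribute and stays open, since the log2 rise over negative control spots was 0.1655 on 1 slide and 0.0674 on the other. No biological explanation was tested.

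HK-2 TGFB1 replicate 1 was far dimmer than every other array. An effect of TGFB1 on total signal is argued against by replicate 2 of the same group, which had 25322 spots well above background. The spike-in slope of 0 on the dim array is consistent with failed labelling or hybridisation, a reading found and tested on the same data.

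Empagliflozin and canagliflozin gave alike fold changes in both lines. Shared control arrays as the whole cause are argued against: the covariance was 0.128 in HK-2 and 0.104 in RPTEC, and the highest of 100 simulations of unchanged groups reached 0.0261 and 0.0262. Each treatment, and the control, held 1 place over the slides of a line. The place of the array on the slide and the treatment therefore cannot be told apart in any comparison within a line. Place may add to the likeness. A shared effect of the inhibitors remains open beside it as a hypothesis.

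Other splits of the samples were counted for the means of both lines, with 8 arrays each and line as a term. All 34 splits gave as many genes as the real one for TGFB1 (real 0, highest other 0), for empagliflozin (real 0, highest other 2276) and for canagliflozin (real 0, highest other 1568). With a real count of 0 every split reaches it by construction, so these counts say nothing for or against chance. The split by replicate number gave the 2276 and the 1568, a structure of the samples that follows the slides. Among the 8 splits that part the arrays of every slide, fitted with slide terms, empagliflozin had 10 genes against a highest other of 0 (1 of 8 splits as large) and canagliflozin 0 against 0 (8 of 8); 8 splits are too few for a share under 0.05, and a real count of 0 is again reached by construction.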

How the results depend on the processing

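All fits on 15 arrays with slide terms, the fits that left out constant genes and the smaller floor were chosen after seeing the data. The cause of the changes listed here was not tested unless stated. The replicate block and the slide as block are the same fit except for the untreated lines, so their equal values are not separate results.

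Over all 16 arrays TGFB1 in HK-2 gave 49 genes, and 2 with normexp (1 higher, 1 lower), 32 with the deposited values and 145 without a filter. It gave 0 with the strict filter, 0 with each line fitted alone with or without constant genes, and 225 with slide terms. TGFB1 in RPTEC gave 2, and 0 with normexp, the deposited values and the strict filter, 6 without a filter and 5 with RPTEC alone without constant genes. The mean of both lines for TGFB1 gave 30, and 1 with normexp, 17 with quantile normalization (14 higher, 3 lower) and 70 without a filter. It gave 0 with the strict filter, 107 with slide terms and 22 with the deposited values (16 higher, 6 lower). The difference of TGFB1 between lines gave 0, and 4 with the deposited values, 23 without a filter and 3 with slide terms. The lines differed in 1691 genes, and 67 with the strict filter, which tests 3342 genes; normexp gave 719 higher and 733 lower against 995 and 696.

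Without a filter the inhibitors moved from 0 genes to 5 (empagliflozin in HK-2), 12 (empagliflozin in RPTEC), 4 (canagliflozin in HK-2), 9 (canagliflozin in RPTEC), 1 and 2 (their direct comparison in HK-2 and RPTEC), 4 and 2 (differences between lines) and 4 and 2 (means of both lines). The deposited values gave 1 gene for each inhibitor in RPTEC, and RPTEC fitted alone gave 1 for each, or 9 and 1 without constant genes. The canagliflozin mean gave 1 with slide terms on all 16 arrays. With these terms every inhibitor comparison within a line kept a count of 0.

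With the 15-array fit and its versions with the deposited values, normexp, quantile normalization, trended robust variances, the smaller floor and probes above background on all 15 arrays, the counts were as follows, in that order. TGFB1 in HK-2: 1959, 1877, 2366, 1822, 2175, 1809, 1655; TGFB1 in RPTEC: 197, 238, 381, 145, 233, 108, 132. Empagliflozin in HK-2: 1030, 1210, 1003, 1011, 1443, 919, 1160, and in RPTEC 694, 611, 947, 665, 800, 467, 432. Canagliflozin in HK-2: 1137, 1237, 1077, 1162, 1571, 891, 1240, and in RPTEC 605, 455, 849, 530, 685, 424, 458. Differences between lines for TGFB1: 705, 589, 889, 589, 780, 607, 524, for empagliflozin 188, 185, 272, 165, 196, 81, 88, and for canagliflozin 120, 226, 389, 108, 250, 39, 134. Means of both lines for TGFB1: 1933, 1925, 2428, 1796, 2148, 1745, 1607, for empagliflozin 1794, 1740, 1895, 1785, 2105, 1548, 1564, and for canagliflozin 1754, 1646, 1710, 1725, 2056, 1538, 1522. Their direct comparison in RPTEC gave 16, 0, 0, 13, 7, 1, 0, so its 16 genes depend on the processing, and in HK-2 it gave 1 with the smaller floor and 0 otherwise.

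The 15-array calls of the inhibitors in HK-2 rest on a spread shared with RPTEC: with HK-2 alone and slide terms both inhibitors gave 0 genes, with or without constant genes. In RPTEC alone empagliflozin gave 248, or 562 without constant genes, canagliflozin 168, or 449, TGFB1 2, or 62, and the direct comparison 0, or 5. TGFB1 in HK-2 alone gave 498, or 810.

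Of 275 list tests, which leave out those between the untreated lines, 50 passed, 39 of them within a line. The strict filter left 23 and 20 and an estimated correlation 6 and 6. An estimated correlation in the 15-array fit left 1 and 1. TGFB1 genes of the other line gave 1 call of a list, and 3 with quantile normalization or trended robust variances, 2 with the deposited values, without a filter, with the mean of probes or with either block, 0 with each line alone or an estimated correlation, 6 in the 15-array fit with the preset correlation and with the deposited values, 4 there with each line alone and 0 there with an estimated correlation; normexp and the strict filter gave too few genes for a value.

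Leaving out 1 array at a time gave 1 to 11785 genes for TGFB1 in HK-2 (1 without HK-2 control replicate 1, 8 without control replicate 2, 291 without TGFB1 replicate 1 and 11785 without replicate 2, which leaves the dim array alone and explains the size). It gave 0 to 12 for TGFB1 in RPTEC (0 without control replicate 1 or either TGFB1 array, 1 without control replicate 2, which was a fall, 12 without the dim array), 0 to 0 for empagliflozin in HK-2, 0 to 33 in RPTEC (33 without the dim array, 1 without control replicate 2), 0 to 1 for canagliflozin in HK-2 (1 without canagliflozin replicate 2) and 0 to 8 in RPTEC (8 without the dim array, 1 without control replicate 2). The direct comparisons gave 0 to 1 (HK-2, 1 without canagliflozin replicate 2) and 0 to 6 (RPTEC, 6 without the dim array), the differences between lines 0 to 10533, 0 to 2 and 0 to 0 (28 and 2 without the dim array, 10533 without HK-2 TGFB1 replicate 2), the controls 904 to 5243 (5243 without the dim array, 925, 904, 1116 and 977 without each control), the means 1 to 10547, 0 to 5 and 0 to 8 (260, 5 and 8 without the dim array), list calls 31 to 61 and 25 to 49 within a line (31 without HK-2 control replicate 2), and the lists of TGFB1 genes 0 to 4. A group left with 1 array was assumed to vary like the others.

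Some directions turned, with ranges here over the fits that left out 1 array. SLC5A2 with TGFB1 in HK-2 ranged from -0.41 (without the dim array) to 2.54 (without TGFB1 replicate 2) around 1.06, and was -0.072 with normexp on 15 arrays. LRP2 ranged from -1.98 (without the dim array) to 6.66 (without TGFB1 replicate 2). It was -2.28 in the 15-array fit, with trended robust variances, the smaller floor, probes above background on all 15 arrays or HK-2 alone, -1.81 with the deposited values, -1.74 with normexp and -2.17 with quantile normalization. GADD45B ranged from -0.83 to 2.48 and P4HA2 from -1.28 to 2.11, lowest without TGFB1 replicate 2, and P4HA2 was -0.082 with normexp. THBS1 with TGFB1 in RPTEC ranged from -0.088 (without control replicate 1) to 0.72.

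With empagliflozin in HK-2, SLC5A2 ranged from -0.71 to 0.42 (0.27 without control replicate 1, 0.42 without empagliflozin replicate 2) and VCAM1 from -3.02 to 0.075 (highest without empagliflozin replicate 1). With canagliflozin in HK-2, SLC5A2 ranged from -0.46 (without canagliflozin replicate 1; -0.38 without control replicate 2) to 0.53, VCAM1 from -2.96 to 0.036 (highest without canagliflozin replicate 1) and THBS1 from -0.88 to 0.0013 (highest without canagliflozin replicate 2). SLC5A2 between the lines ranged from -0.64 to 0.20, highest without HK-2 control replicate 1. With empagliflozin in RPTEC, THBS1 ranged from -0.90 to 0.085, TNC from -1.16 to 0.43 and PDGFB from -0.64 to 0.099, each highest without empagliflozin replicate 1; without control replicate 2 TNC was 0.12 and PDGFB 0.083. With canagliflozin in RPTEC, THBS1 ranged from -0.90 to 0.24 and TNC from -1.10 to 0.058, highest without canagliflozin replicate 1, and THBS1 was 0.077 without control replicate 2.

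Among lists, proximal tubule transport with canagliflozin in HK-2 had a median of 0.051 under the strict filter and ranged from -0.65 to -0.077. The NF-kB list with canagliflozin in HK-2 ranged from -0.44 to -0.019, and without canagliflozin replicate 1 its test turned upward without passing. The proliferation list in RPTEC ranged from -1.23 to 0.35 for empagliflozin (0.35 without empagliflozin replicate 1, passing upward, 0.12 without control replicate 2) and from -1.37 to 0.41 for canagliflozin (0.41 without canagliflozin replicate 1, passing upward, 0.053 without control replicate 2). Those fits have no slide terms. Within slides the medians were -0.65 (0 of 39 genes positive) and -0.15 (6 of 39) for empagliflozin, and -0.80 (0 of 39) and -0.20 (11 of 39) for canagliflozin.

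Of the values of single genes and of gene lists, counted together, 1830 kept direction and side of the threshold under the analyses fixed in advance, 154 fell back over it, 46 passed it and 2 reversed. Leaving out arrays gave 837, 104, 49 and 26, and the later analyses 813, 92, 706 and 10. Signal over background limits the rest: HK-2 TGFB1 replicate 1 had 5250 spots well above background.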
